A study of Mus musculus with 2 samples.

How the data were processed

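Single-cell RNA was measured in sorted mouse leukemia progenitors named I1DN in the labels, gated as cKit positive and Cd11b negative. Mice received AG-120, an inhibitor of mutant IDH1 also known as ivosidenib, or its vehicle for 5 days. Each treatment has 1 library, so 2 libraries were compared.

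Per the labels' protocols, cells were loaded on separate channels of a 10x Genomics Chromium instrument, and the libraries were pooled and sequenced on a NovaSeq 6000. The protocol names a 5′ kit, whereas the design text speaks of a 3′ platform. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 4.0.4 were used with the mouse build mm10/GRCm38. The file headers give software version 3.0.2. The deposited matrices hold raw UMI counts, which the authors made as whole numbers per gene and cell barcode without normalization, per the file headers. They list 31053 genes with Ensembl identifiers and symbols, of which 30934 identifiers were found in GENCODE mouse release 21, the source of gene positions (GRCm38) and transcript lengths.

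The matrices hold 4146 vehicle and 4016 AG-120 barcodes. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 3914 vehicle and 3756 AG-120 cells. Doublets were scored with Scrublet through scanpy 1.11.5 and stayed in. Scrublet marked 3 vehicle cells and 1 AG-120 cell, too few for such a loading, so it is treated as not having worked here.

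Gene ratios were computed from UMIs summed over all kept cells of a library and scaled to a common library total (CPM). A gene was measured when its UMIs reached 500 over both libraries. Its AG-120/vehicle ratio carries an exact conditional binomial 95% interval. A gene is described as higher or lower at 1.2-fold or more, which is a description and not a test. With 1 library per treatment no p-value was computed, cells were not used as replicates, and all intervals cover counting error only. Every difference therefore compares 2 libraries, not 2 conditions, and has no replicate check.

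Gene lists were fixed before the data were examined, as were the main alternatives and the rule for named genes. For each list the median log2 ratio over its measured members is given with an interval from 1000 Poisson redraws. Its percentile comes from 10000 random lists of equal size matched on mean expression within 100 ranks. The main lists were S phase, G2/M phase, cell cycle brakes and quiescence, stem cell, HOXA and leukemia stem cell, primary granule, secondary granule, pyrimidine salvage and type I interferon response. Named genes were the 12 highest and 12 lowest ratios, leaving out gene models, mitochondrial, ribosomal protein and sex-linked genes. The rule also names up to 12 members of each main list, up to 4 of each other list, and Idh1, Dnmt3a, Nras, Kit and Itgam. The text gives a part of these, and says where a gene lies outside the rule; 2 genes are not reported here. Median scaling shifts every log2 ratio by the median over all genes, which is −0.12, so a gene at −0.12 has the typical ratio.

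Cells of both libraries were clustered together on 2000 variable genes chosen within each library. Cell cycle, histone, mitochondrial, ribosomal protein and sex-linked genes were left out. The clustering took 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2). A cluster's candidate class was the one with the largest share of its fixed markers at 20 CPM or more and at 20% or more of the highest cluster, with at least 3 markers and 50% of the list. The cluster was called X-like when the 10 genes that led it against clusters of other candidates held a marker of that class and no more markers of any other class. The thresholds of this naming were set after the data were seen. For shares of cells with a UMI and for cell cycle phases, each cell was thinned to 6500 UMIs. At that depth 361 vehicle and 131 AG-120 cells were too shallow and left out. Shares carry exact Clopper-Pearson 95% intervals. Phases were called with scanpy from the S and G2/M lists on both libraries together.

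Within classes, UMIs of each list were summed and compared as log2 ratios. The fixed minimum of 50 cells in each library was met by 0 classes or clusters, so a minimum of 20, chosen after the data were seen, was used and gave 5 comparisons, of named classes and of unnamed clusters; clusters of a named class were compared only as that class. No cluster could be named HSC/MPP-like, so the comparison fixed for that class was not made.

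The steps were tested on simulated data with 200 changed genes among the real means and totals. Of the simulated ratios, the interval held the true value for 95.0% of 9206 unchanged genes. All of the genes changed 1.5-fold, 2-fold or 4-fold were called in the right direction (100%), and 52% of those changed 1.2-fold, since that fold is the threshold itself. A simulated list of 25 genes raised 1.5-fold lay at percentile 100, and 7 of 100 unchanged lists fell outside the central 95%. Simulated counts were Poisson draws with all genes but the 200 unchanged, whereas the real genes had a median log2 ratio size of 0.49. These simulations therefore check the computation only. They do not show how the intervals or percentiles behave with spread among cells or mice. Thinning brought simulated cells of 5050 and 3611 detected genes to 2406 and 2407.

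Alternatives covered the cell filter, Scrublet calls, scaling, the weight of cells, thinning, the low-count filter, clustering settings and a weighting of AG-120 classes by vehicle class shares. That weighting equalises classes but not the clusters within a class, so its values are no full control for the cell mixture. Clustering after thinning, clustering without the fixed markers, the 20-cell minimum and removal of a transcript length trend were added after the data were seen.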

Results

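Gene expression was counted in single I1DN leukemia progenitors from mice treated with vehicle or AG-120, with 1 library per treatment. The vehicle library held 56821757 UMIs over 4146 barcodes and the AG-120 library 96919988 over 4016. Kept cells had a median of 13156.5 UMIs and 3567 genes in the vehicle library, against 25681.5 UMIs and 4707 genes in the AG-120 library. The submitters state that the experiment asks how far transcriptional responses to AG-120 vary among cells. With no replicate library, each value below describes these 2 libraries, and intervals cover counting error only.

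The libraries were made of different cells. Erythroid-like cells were 88.4% of AG-120 cells (95% interval 87.4 to 89.4, 3321 of 3756) and 1.02% of vehicle cells (0.731 to 1.39, 40 of 3914). Megakaryocyte-like cells were 29.4% of vehicle cells (28.0 to 30.9) and 1.09% of AG-120 cells (0.784 to 1.48), and ranged over other clusterings from 13.7% to 30.6% and from 0.0799% to 1.35%. The erythroid-like cells carried Gata1 and Klf1, transcription factors of the red cell lineage, and Ermap, Rhd and Blvrb, genes of red cell membrane and heme breakdown. The megakaryocyte-like cells carried Pf4, a platelet chemokine, and Itga2b, an integrin chain of platelets. Itga2b was not particular to this class, since it was seen in 70.6% of all thinned vehicle cells. Of this class, cluster 3, led by Pf4, held 16.0% of vehicle cells, and cluster 0, led by mitotic genes, 13.4%. Granulocyte-monocyte progenitor-like cells, with Mpo, Elane and Ctsg, were 8.07% of AG-120 cells and 0.204% of vehicle cells, a contrast that other clusterings removed or turned (8.44% and 13.8% with 3000 variable genes). Neutrophil-like cells with Camp and S100a8 were rare in both, at 0.818% of vehicle and 0.586% of AG-120 cells (0 to 6.11% and 0 to 2.77% over other clusterings). No class could be given to 68.5% of vehicle cells and 1.84% of AG-120 cells. Of 14 clusters, 12 drew over 90% of their cells from 1 library, so a cluster may also stand for its library.

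**Figure D1:**
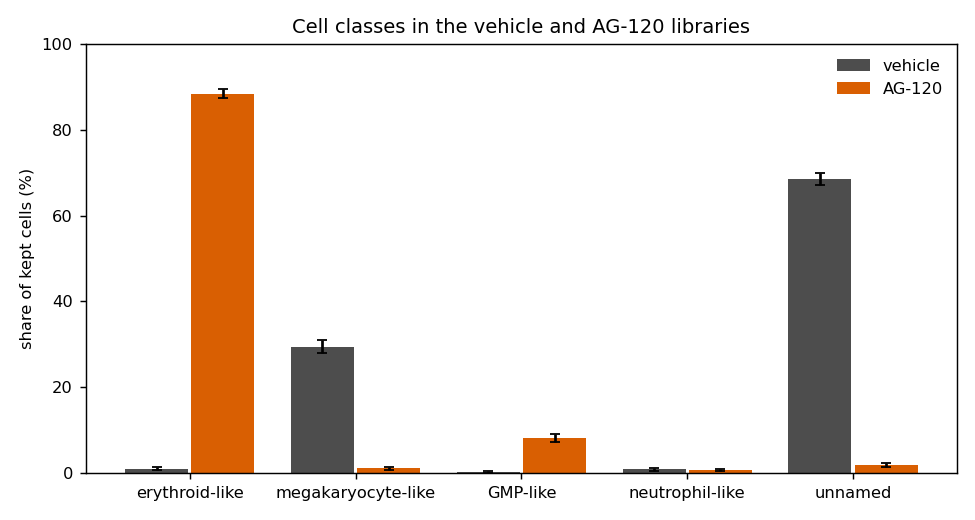
Share of kept cells per class in percent, for the vehicle library (grey) and the AG-120 library (orange); bars start at 0 and error bars are exact 95% binomial intervals. Erythroid-like cells reach 88.4% in the AG-120 library, and unnamed and megakaryocyte-like cells make up 68.5% and 29.4% of the vehicle library.

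The unnamed vehicle cells lay mostly in clusters 1, 2 and 5. Cluster 1 (804 vehicle cells) was led by Cd34, an antigen of blood progenitors, and Ltb, a cytokine of the TNF family, and cluster 2 (1185 vehicle cells) by Sox4, Tox and Ccl5. Cluster 5 (367 vehicle cells) was led by Pclaf, a replication factor, with Cd34 among its first genes. Cluster 4 (84 vehicle cells and 0 AG-120 cells) was led by a histone gene and Upp1. Over both libraries, cluster 7 (242 vehicle and 31 AG-120 cells) held Mpo, Prtn3, MHC class II genes and Prg2, an eosinophil granule gene. These need not come from the same cells, since the eosinophil list was 6.37 higher in log2 in its AG-120 cells. The cluster stayed unnamed because its leading genes held 4 markers of another type beside 3 of granulocyte-monocyte progenitors. Within the megakaryocyte-like class, cluster 0 was led by mitotic genes such as Cenpf, Kif11 and Nusap1, and cluster 3 by Pf4 and Ppbp. The 10 genes that led cluster 0 against all other clusters held 0 megakaryocyte markers, so its name is the weaker. Thinned vehicle cells had means of 7.61 megakaryocyte list UMIs in cluster 0 and 15.7 in cluster 3. In unnamed clusters these means ran from 2.46 (cluster 7) to 5.22 (cluster 4). Among erythroid-like cells, cluster 13 was led by interferon-induced genes such as Isg15, Ifit1, Oasl2, Rsad2 and Irf7.

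**Figure D2:**
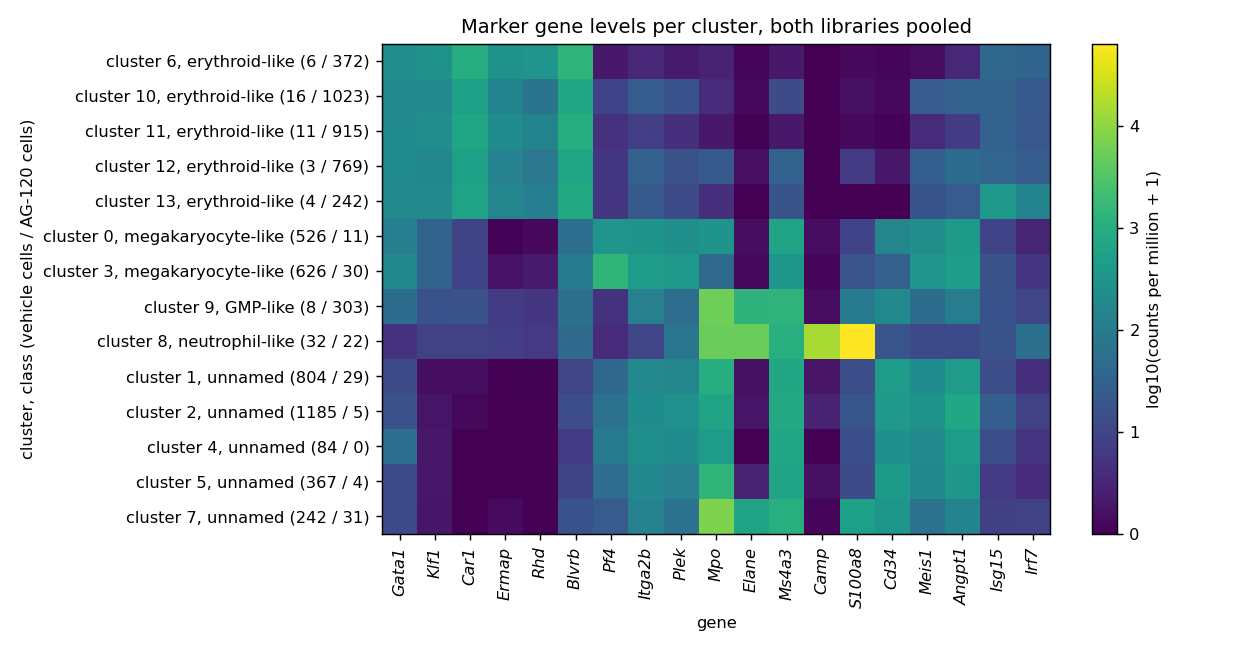
Levels of marker genes (columns) in each cluster (one line each), as log10 of CPM plus 1, with the number of vehicle and AG-120 cells beside each cluster. Gata1, Klf1 and Blvrb are high in clusters 6 and 10 to 13, Pf4 in clusters 0 and 3, and Camp and S100a8 in cluster 8.

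Single markers showed the same split at equal depth, although they are not independent of the classes they helped to name. After thinning to 6500 UMIs, Ermap was seen in 56.1% of AG-120 cells and 0.394% of vehicle cells, and Blvrb in 89.8% and 14.1%. Klf1 was seen in 64.8% and 5.63%, and Gata1 in 66.5% and 22.1%; these last 2 genes were taken from the marker list after their values were seen. Itga2b was seen in 70.6% of vehicle cells and 13.6% of AG-120 cells, and Pf4 in 30.4% and 3.17%. Cd34 was seen in 64.0% of vehicle cells and 5.43% of AG-120 cells. Without thinning, Ermap was seen in 78.0% of AG-120 and 0.664% of vehicle cells, and Cd34 in 7.77% and 71.5%. In neutrophil-like cells, which should lack Ermap, it was seen in 0 of 14 thinned AG-120 cells and 0 of 23 vehicle cells, with intervals up to 23.2% and 14.8% and, over all 22 and 32 such cells, medians of 12334.5 and 12788.5 UMIs before thinning. Blvrb was seen in 2 of these 14 AG-120 cells and in 0 of these 23 vehicle cells, Klf1 and Gata1 in 1 of the 14 each and in 0 of the 23, Itga2b in 1 of the 14 and 1 of the 23, Pf4 in 0 of both, and Cd34 in 0 of the 14 and 4 of the 23.

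Single genes had large ratios in both directions. Over 9419 measured genes, Ermap (ENSMUSG00000028644, chromosome 4, 119175457 to 119190011, GRCm38) was 56.1-fold higher in the AG-120 library (48.3 to 65.7), at 169.67 against 3.02 CPM. Mt2, a metallothionein that binds zinc, was 48.5-fold higher (43.6 to 54.0), and Sphk1, a kinase that makes sphingosine 1-phosphate, 53.6-fold (38.8 to 76.2). Slc38a5, an amino acid transporter, was 50.7-fold higher and Gstm5, a glutathione transferase, 48.1-fold. Ccl24, an eosinophil attractant, had 511 AG-120 UMIs and 1 vehicle UMI, a ratio of 299 with an interval from 53.4 to 11837. The other genes of the 12 highest were Gdf3, Prss50, Ccdc68, Slc26a1, Lgals7 and Nectin2, with 4 to 9 vehicle UMIs each. Tox, a nuclear factor of lymphoid development, was 183-fold lower in the AG-120 library (92.2 to 424). Ltb was 27.1-fold lower (25.6 to 28.7), at 342.21 CPM in the vehicle library, and S100a4, a calcium-binding protein, 47.1-fold lower. Thsd1, Zfp467, Gcnt2, Cd180, Srgap3, Adgrl4, Ctla2b and Itgb6 were also among the 12 lowest. Weighted by vehicle class shares, log2 ratios came nearer 0 for Ermap (2.19), Mt2 (3.42), Sphk1 (1.57), Tox (−2.48), Ltb (−1.20) and S100a4 (−0.45). They moved away from 0 for Ccl24 (from 8.22 to 14.2) and Lgals7 (from 5.89 to 7.33). Ccl24 was among the leading genes of cluster 7, which held 31 of the 69 unnamed AG-120 cells that this weighting leans on. With thinned cells Ermap was at 7.67 and Sphk1 at 7.32 in log2, against 5.81 and 5.74 in the main setting.

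Stem and leukemia genes were lower in the AG-120 library. All 5 measured members of the stem cell list were lower, with a median log2 ratio of −4.08 (−4.13 to −4.02), below all 10000 random lists. Angpt1, a ligand of the Tie receptor kinases, stood at 465.32 vehicle and 27.59 AG-120 CPM, and Meis1, a partner of HOX proteins, at 225.53 and 17.25. Mycn had a log2 ratio of −4.42 and Gata2, a factor of early progenitors, −1.66. In the HOXA and leukemia stem cell list 10 of 16 members were lower and 3 higher, with a median of −1.17 at percentile 0.01. Cd34 (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279) was 20.6-fold lower (19.5 to 21.8) and Sox4 10.6-fold lower, whereas Lmo2, a factor shared with erythroid cells, was 1.97-fold higher and Cd47 1.58-fold higher (Lmo2 0.11 in log2 with class weights). With the AG-120 classes weighted by the vehicle class shares, the stem cell median was −1.01 and the HOXA median −0.76.

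Myeloid genes were lower as well. In the primary granule list 9 of 10 measured members were lower (median −1.22, below all random lists), with Mpo, the myeloperoxidase, 3.06-fold lower and Ms4a3 6.44-fold lower, while Elane, neutrophil elastase, was at 1.09-fold (1.03 in log2 with each cell equal, 0.85 with thinned cells). All 13 measured members of the secondary granule list were lower (median −1.88, below all random lists), and a few cells carry that list: the 32 vehicle neutrophil-like cells held 105462 of 116296 UMIs and the 22 AG-120 ones 45888 of 56609. Its lower genes included Cxcr2, a chemokine receptor (16.1-fold), Camp (7.44-fold) and S100a8 (4.68-fold). The median was −1.52 for myeloid transcription factors (11 of 13 lower) and −2.51 for monocyte genes (6 of 7 lower). All 8 measured megakaryocyte genes were lower (median −3.24), with Pf4 11.1-fold, Itga2b 9.27-fold and Plek 15.4-fold lower. With each cell equal, log2 values were −2.44 for the megakaryocyte median, −1.74 for the monocyte median, −2.11 for Pf4 and −1.51 for Camp. Of 13 erythroid genes, 11 were higher (median 3.29, above all random lists), with Rhd 30.5-fold, Blvrb 17.8-fold and Car2, a carbonic anhydrase, 3.05-fold higher. The directions of the granule lists depend on the cells present. Weighted by vehicle class shares their medians were 0.67 and 0.80, those of the myeloid factor and monocyte lists 0.43 and 0.58, and log2 ratios were 0.73 for Mpo, 1.10 for S100a8, 1.69 for Pf4 and −0.58 for Car2. The megakaryocyte median came under 1.2-fold, at −0.14, with Itga2b at −0.31 and Plek at −0.87; that weighting rests on 69 unnamed AG-120 cells, 31 of them in cluster 7.

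Genes of DNA replication and mitosis went both ways, and inhibitors of the cell cycle were lower. The series title concerns the cycling of leukemia stem cells. In the S phase list 15 of 43 members were higher and 10 lower (median 0.10, percentile 62.4). Gmnn, the licensing inhibitor geminin, was 1.80-fold higher and Cdc6, a loading factor of replication origins, 1.64-fold higher, while Hells, a chromatin helicase, was 1.79-fold lower and Mcm6 had a log2 ratio of −0.20. In the G2/M list 20 of 54 members were higher and 18 lower (median 0.00, percentile 45.7), with Tubb4b, a tubulin, 2.09-fold and Ube2c, a ubiquitin enzyme of mitosis, 1.63-fold higher, Gas2l3 3.79-fold lower and Hmgb2 at 0.02. Of 16 measured brakes and quiescence genes 14 were lower and 0 higher, with a median of −0.79 (−0.83 to −0.74) at percentile 0.26. Ccng2 was 6.97-fold lower, Btg2 4.07-fold, and the kinase inhibitors Cdkn1a, Cdkn2d, Cdkn1b and Cdkn2c were 3.51-fold, 3.04-fold, 2.23-fold and 1.73-fold lower. Weighted by vehicle class shares the brake median was −0.15 and the S and G2/M medians −0.07 and −0.25, with Cdkn1a at 0.79, Cdkn2d at 0.01, Gas2l3 at 0.25 and Cdc6 at −0.04 in log2. The median of G1 cyclins and kinases was −0.19 and that of histone genes −0.14.

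At equal depth, cycle transcripts made up a larger share of the UMIs of AG-120 cells. Thinned cells of the AG-120 library had a median of 46 G2/M list UMIs (mean 49.3) against 20 (mean 40.1) in the vehicle library, and 28 S list UMIs (mean 28.5) against 21 (mean 25.6). Brake genes had a mean of 2.60 UMIs per thinned AG-120 cell and 5.29 per vehicle cell. Since every thinned cell has the same total, these values are shares of a cell's RNA and not amounts per cell. Phase calls put 43.4% of AG-120 cells (41.8 to 45.1) and 21.4% of vehicle cells (20.1 to 22.8) in G2/M, and 48.3% and 39.5% in S. Without thinning, G2/M held 41.0% and 20.4% and S held 52.1% and 39.3%. Calls in erythroid-like cells were alike, with 44.5% of 3247 AG-120 and 47.4% of 38 vehicle cells in G2/M (interval 31.0 to 64.2). Megakaryocyte-like cells had 46.4% of 1088 vehicle and 41.2% of 34 AG-120 cells in G2/M, and unnamed vehicle cells had 9.30%. That contrast between vehicle classes follows how cells were clustered. Within the megakaryocyte-like class, G2/M held 88.6% of vehicle cells in the mitotic cluster 0 and 9.33% in cluster 3. In unnamed clusters it held from 0.821% (cluster 2) to 47.4% (cluster 4) of vehicle cells. Weighted by vehicle class shares, the AG-120 share in G2/M was 25.3%. The split between S and G2/M was unstable: scored within each library, the AG-120 library had 26.3% in S and 60.4% in G2/M, and free RNA enters such calls, so they are not read as a rate of cycling.

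Ribosome, heme and nucleotide genes were higher in the AG-120 library. All 25 measured genes of the MYC target and ribosome biogenesis list were higher (median 0.92, above all random lists), with Npm1 and Ncl, nucleolar proteins, 2.16-fold and 1.89-fold and Odc1, the first enzyme of polyamine synthesis, 3.22-fold higher. Weighted by vehicle class shares the medians of the ribosome, purine and de novo pyrimidine lists were under 1.2-fold (0.16, 0.02 and 0.12), that of the heme list was 0.68, and Ncl and Odc1 were at 0.06 and 0.25 in log2. The heme and iron list had 10 of 13 members higher (median 1.56), Cpox, an enzyme of heme synthesis, 8.07-fold. The de novo pyrimidine list had 12 of 17 members higher (median 0.54, percentile 99.6) and the purine list 9 of 14 (median 0.57, percentile 99.4). Pyrimidine salvage genes went both ways, 8 of 18 higher and 7 lower (median 0.14, percentile 86.4). Cda, cytidine deaminase, was 13.8-fold, Cmpk2, a mitochondrial nucleotide kinase induced by interferon, 6.23-fold, the nucleoside transporter Slc29a1 3.03-fold and Uck2 1.96-fold higher. Upp1, uridine phosphorylase, was 7.82-fold lower and Tk1 1.37-fold higher, and both turned with the class weighting, to 0.70 and −0.07 in log2.

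Type I interferon genes were higher, with 17 of 26 members higher and 7 lower, a median of 0.61 (0.55 to 0.64) above all random lists, and 0.57 with vehicle class weights. That weighting does not equalise the cell mixture, as it leans on 69 unnamed AG-120 cells, 31 of them in cluster 7. Cluster 7 held 242 of the 2682 unnamed vehicle cells, and its interferon list sum had the highest ratio within classes (1.76). Oasl1 was 10.6-fold (7.61 to 15.3), Irf7, a regulator of interferon genes, 6.83-fold, Isg15 3.87-fold and Ifitm3 2.89-fold higher, while Ifi203 was 10.4-fold and Usp18, a brake on interferon signalling, 3.82-fold lower. The interferon gamma and MHC list had a median of −0.30, which was 0.02 with each cell weighted equally. Medians were −0.86 for TNF and NF-kB response genes, −0.58 for immediate early genes, and these were 0.17 and 0.34 with the class weights. Of 9 RAS/MAPK feedback genes 7 were lower and 0 higher, with a median of 0.07 once class weights were used. Heat shock genes had a median of 0.58 (8 of 12 higher), TCA cycle genes 0.43 (17 of 22 higher) and oxidative phosphorylation genes 0.24 (percentile 62.1); with the class weights these were 0.10, 0.12 and 0.06. Glycolysis had a median of −0.24, with Pkm, pyruvate kinase, 6.53-fold lower; both turned with the class weights, to 0.39 and 0.05 in log2. Medians, with class-weighted values in parentheses, were −0.55 (−0.07) for cholesterol synthesis, −0.20 (0.04) for fatty acid metabolism and −0.36 (0.39) for hypoxia. In the same way they were −0.30 (0.17) for p53 targets and −0.25 (0.53) for the unfolded protein response. NRF2 targets had a median of 0.29 (0.05 without the length trend) and apoptosis regulators one of 0.03 (−0.23 with each cell equal). The hypoxia list sum went against its median, at 2207 AG-120 and 1502 vehicle CPM. Within classes that sum was higher in 4 of 5 comparisons and lower in 0 (0.23 to 0.58).

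**Figure D3:**
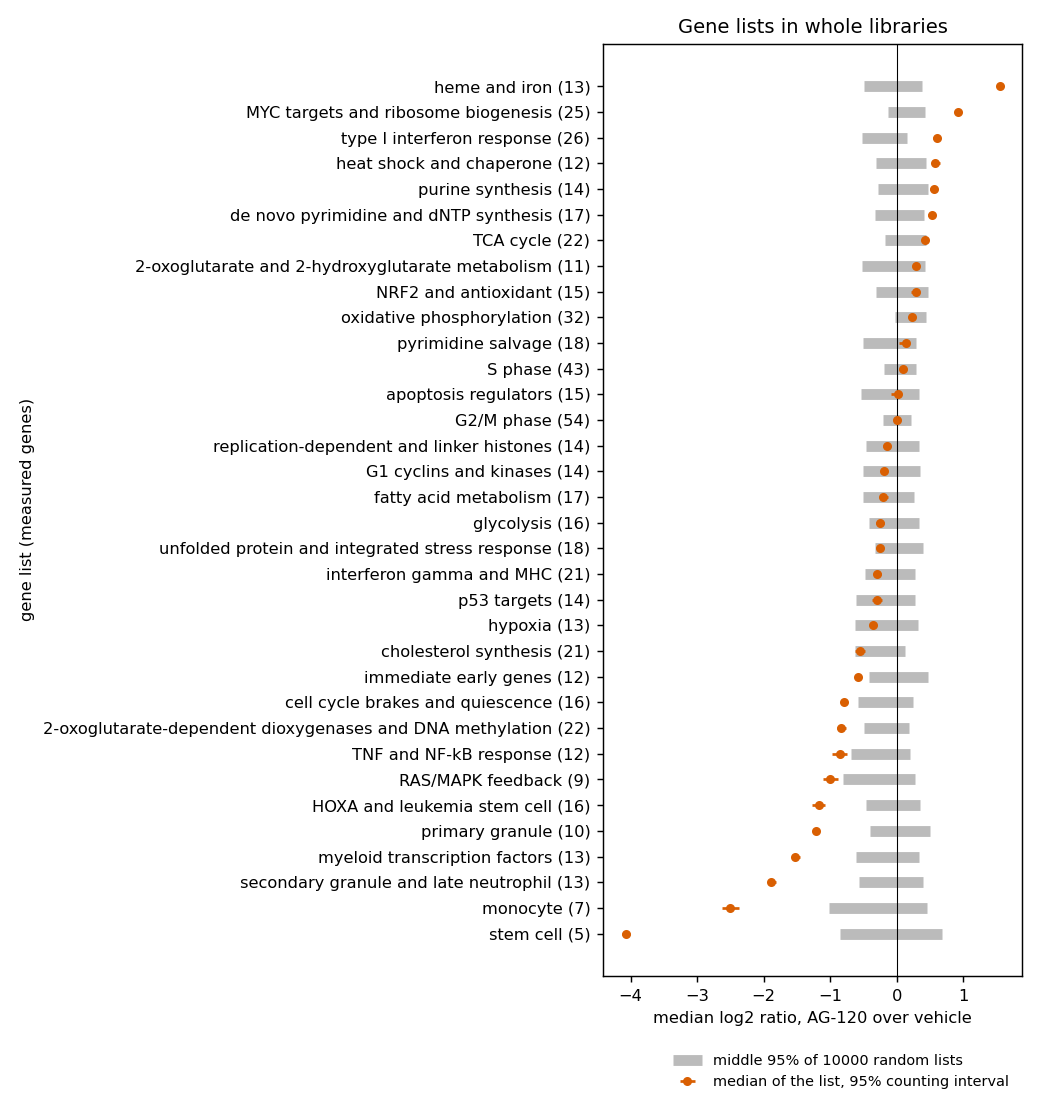
Median log2 ratio, AG-120 over vehicle, of each gene list (points, bars are 95% counting intervals, measured genes in parentheses) with the middle 95% of 10000 matched random lists (grey). The heme list lies at 1.56 and the stem cell list at −4.08, both outside the grey range, and the S phase list at 0.10 inside it.

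The genes of the leukemia model and its inhibitor pathway were read too. Idh1 (ENSMUSG00000025950, chromosome 1, 65158616 to 65186500) was 1.80-fold lower in the AG-120 library (1.72 to 1.89), Dnmt3a, a DNA methyltransferase, 2.67-fold lower, and Nras had a log2 ratio of −0.02. These counts do not separate mutant from normal alleles. With vehicle class weights Idh1 was at 0.56, Dnmt3a at −0.57 and Nras at −0.32 in log2. Those weighted values lean on 69 unnamed AG-120 cells, 31 of them in cluster 7. Among genes of 2-oxoglutarate and 2-hydroxyglutarate metabolism 6 of 11 were higher and 4 lower (median 0.29, and 0.19 with the class weights). Idh2 was 1.64-fold lower, and at −0.02 in log2 with the class weights. Of 22 genes of 2-oxoglutarate-dependent dioxygenases and DNA methylation 17 were lower and 1 higher (median −0.84, percentile 0.01, and −0.46 with the class weights). Within classes the sum of that list was at −0.20 in erythroid-like and −0.21 in megakaryocyte-like cells. It was at −0.29 in cluster 1, −0.42 in cluster 7 and 0.19 (−0.12 to 0.50) in neutrophil-like cells. Kit and Itgam had log2 ratios of −0.94 and −2.56, but both encode antigens of the sort, so they carry no finding here.

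Within the few cells that could be compared, lists varied among classes. The comparisons were erythroid-like (40 vehicle, 3321 AG-120 cells), megakaryocyte-like (1152, 41), neutrophil-like (32, 22), cluster 1 (804, 29) and cluster 7 (242, 31). The interferon list was higher in megakaryocyte-like cells (0.83, 0.72 to 0.94), neutrophil-like cells (0.80, 0.56 to 1.05), cluster 1 (0.53, 0.38 to 0.68) and cluster 7 (1.76, 1.64 to 1.88), and was at 0.03 (−0.05 to 0.12) in erythroid-like cells. That last value leans on a few vehicle cells, 4 of the 40 being in cluster 13: thinned vehicle erythroid-like cells had a mean of 9.95 and a median of 4 UMIs of the list, against 6.40 and 5 in AG-120 cells. The stem cell list was lower in erythroid-like cells (−0.92), megakaryocyte-like cells (−0.97), cluster 1 (−0.76) and cluster 7 (−1.53). In neutrophil-like cells it stood at −0.98, from 21 and 7 UMIs, with an interval from −2.46 to 0.30. Single genes of cluster 1, the Cd34 cluster, had log2 ratios of −1.14 for Cd34, −1.04 for Angpt1, 3.03 for Isg15 and 0.65 for Npm1. In megakaryocyte-like cells these were −1.81, −2.01, 2.18 and 0.55. The ribosome biogenesis list was at 0.50 in megakaryocyte-like cells, 0.44 in neutrophil-like cells, 0.45 in cluster 1, 0.16 in erythroid-like cells and −0.68 in cluster 7.

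Cycle lists had no common direction within classes. The G2/M list was at −0.30 in erythroid-like, −0.42 in megakaryocyte-like and −0.13 in neutrophil-like cells, but at 0.35 in cluster 1 and 0.42 in cluster 7. The megakaryocyte-like value mixes the mitotic cluster 0 with cluster 3; in cluster 3 alone thinned AG-120 cells had a higher mean of G2/M UMIs (37.6 against 27.9). The S list lay between −0.20 and 0.14 in all comparisons but cluster 7, where it was −0.72. Brakes were at −0.20, −0.21 and −0.24 in erythroid-like cells, megakaryocyte-like cells and cluster 1, at 0.18 (−0.07 to 0.43) in neutrophil-like cells and at 1.08 (0.90 to 1.25) in cluster 7. In cluster 3 alone thinned cells had means of 5.43 brake UMIs in the AG-120 and 5.56 in the vehicle library. Pyrimidine salvage was at 0.59 (0.32 to 0.86) in neutrophil-like cells, from 228 vehicle and 226 AG-120 UMIs, and between −0.14 and 0.18 elsewhere. The HOXA list was at −0.27, −0.24, 0.15, −0.51 and −0.96 in the order of the comparisons, and the primary granule list at 0.19, −0.25, −0.46, 0.02 and −0.09. Cells of a class were not alike in the 2 libraries. Of the megakaryocyte-like cells, cluster 3 held 626 of the vehicle cells and 30 of the AG-120 cells, and the AG-120 cells had more erythroid list RNA (1.49) and more megakaryocyte list RNA (1.34). In cluster 7 the AG-120 cells had more eosinophil (6.37) and secondary granule (4.13) list RNA, so its values compare different cells. Elsewhere the secondary granule list was lower, at −1.14, −0.60 and −1.58 in megakaryocyte-like and neutrophil-like cells and cluster 1. It was at −0.57 in erythroid-like cells, where few UMIs of the 40 vehicle cells carry it. The dendritic list was at 3.77 in cluster 7, from 3115 vehicle and 3513 AG-120 UMIs. Few UMIs carry it elsewhere. It was at 6.22 (4.64 to 8.51) in neutrophil-like cells, from 3 and 147 UMIs. In cluster 1 it was at 2.07 (1.18 to 2.87), from 91 and 15 UMIs. It was at −0.43 (−1.80 to 1.46) in erythroid-like and −0.02 (−3.10 to 1.91) in megakaryocyte-like cells. In cluster 1 the T/NK list was at 2.06 and the megakaryocyte list at −0.78. In erythroid-like cells the megakaryocyte list was at −1.70, the lymphoid-primed list at −1.20 and the erythroid list at −0.58. The erythroid list was higher in AG-120 neutrophil-like cells (3.13, 2.31 to 4.07), a cell type that should lack these genes.

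**Figure D4:**
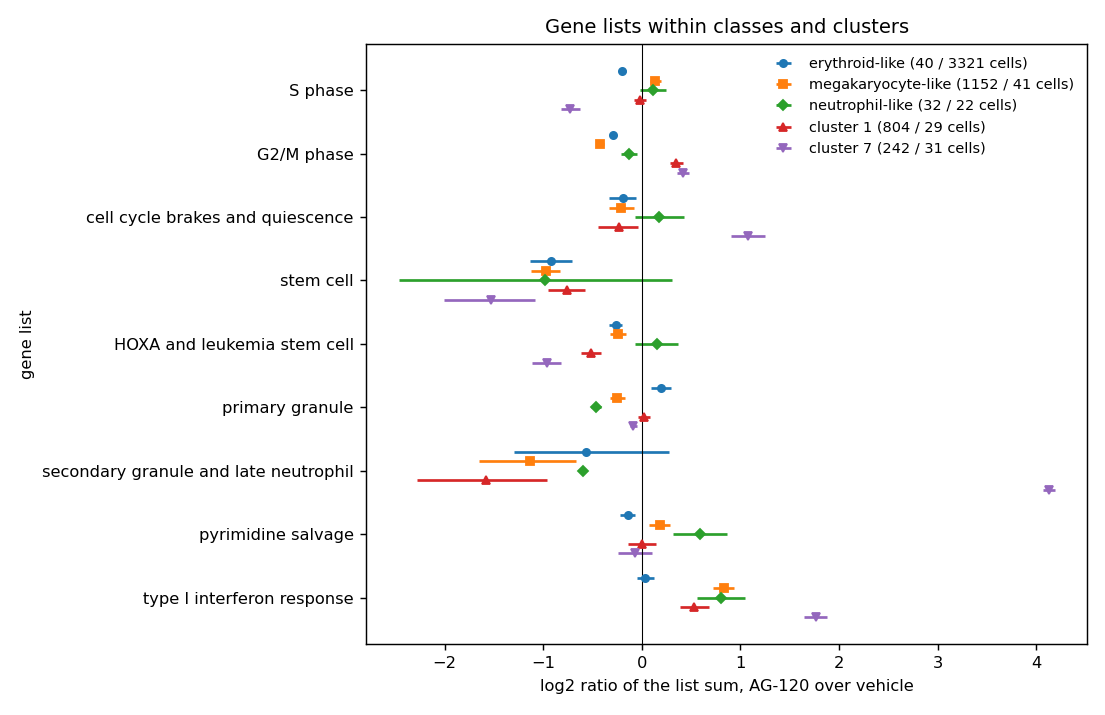
Log2 ratio of the UMIs of each main list, AG-120 over vehicle, within the named classes and the unnamed clusters that hold at least 20 cells in each library; bars are exact 95% counting intervals and cell numbers are vehicle / AG-120. The interferon list lies at 0.83 in megakaryocyte-like and at 0.03 in erythroid-like cells, and cluster 7 stands apart at 4.13 for the secondary granule list.

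Very short transcripts were lower in the AG-120 library. Rps29 and Rpl39, proteins of the ribosomal subunits, were 2.90-fold (2.88 to 2.92) and 2.27-fold lower, and Tomm7, a part of the mitochondrial import pore, 1.48-fold lower; these 3 genes lie outside the rule for names and were chosen after their values were seen. A gene's length was taken as the median length of its annotated transcripts in the basic GENCODE set. Of 30 measured genes of at most 400 nucleotides, 28 were lower and 1 higher. The difference of their median log2 ratio from that of longer genes was −0.83. The difference of medians was −0.84 in erythroid-like, −0.97 in megakaryocyte-like and −1.17 in neutrophil-like cells, −0.68 in cluster 1 and −0.95 in cluster 7. Genes of 600 to 1500 nucleotides had a median log2 ratio of 0.16 over the libraries, and genes over 6000 nucleotides one of −0.43. With this length trend removed, the medians of the main lists kept their directions, while those of apoptosis regulators (−0.19) and of fatty acid metabolism (0.026) crossed 0.

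**Figure D5:**
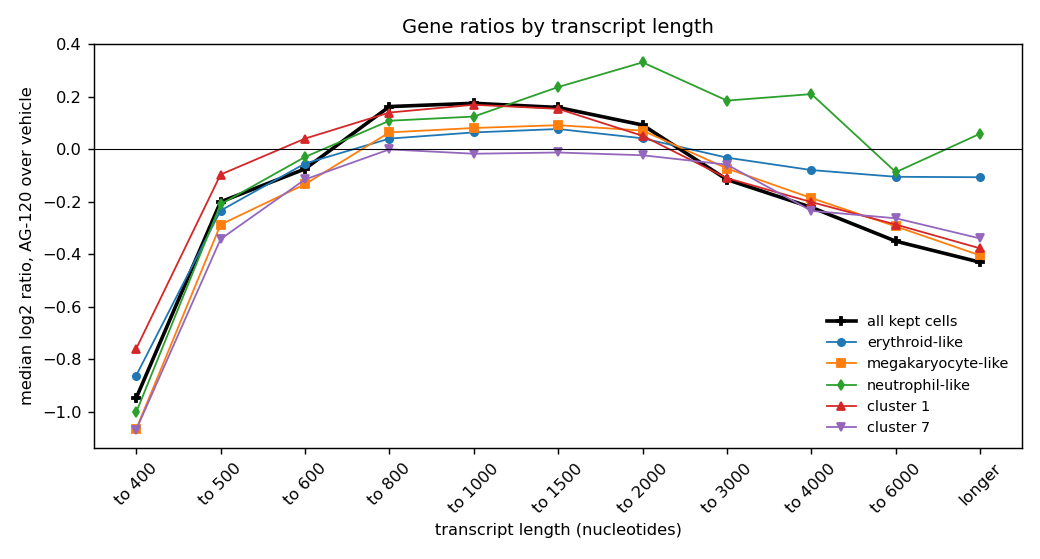
Median log2 ratio, AG-120 over vehicle, of genes grouped by transcript length in nucleotides, for all kept cells (black) and for the 5 classes and clusters compared. Genes of at most 400 nucleotides lie lowest in all 6 lines, at −0.95 over all kept cells.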

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

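Clustering after thinning, clustering without the fixed markers, the 20-cell minimum and the removed length trend were chosen after the data were seen; the other alternatives were not. The main results kept a value within the counting interval in 91 of 177 alternatives. No paired analysis was possible because each treatment has 1 library and no test was made. Not possible were alternatives for HSC/MPP-like cells, which no cluster could be named, and those for classes of 50 cells, of which there were 0. The filter that keeps all barcodes was not run within classes. Leaving out Scrublet calls removes 4 cells and says little about doublets. Depth limits the comparisons within classes, since 22 to 41 AG-120 or vehicle cells carry each of them.

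Erythroid-like cells stayed the main class of the AG-120 library at every clustering, and the cause of the smaller moves was not tested. Their share was 80.7% with all barcodes, 84.7% at resolution 1.5, 86.4% with 3000 variable genes, 86.6% without the fixed markers, 87.1% after centring each library, 87.1% with another seed and 89.6% after thinning. In the vehicle library it was 1.76% after centring and 1.42% with all barcodes. Megakaryocyte-like cells were 13.7% of vehicle cells at resolution 0.5, 19.5% at resolution 1.5, 22.6% with 1000 and 15.05% with 3000 variable genes, 27.1% with another seed, 24.1% with all barcodes and 23.7% without Scrublet calls. In the AG-120 library they were 0.772% at resolution 0.5, 0.745% with 3000 variable genes and 0.0799% after centring. Granulocyte-monocyte progenitor-like cells ranged from 0 to 13.8% of vehicle cells and from 0 to 9.90% of AG-120 cells, so that class has no stable size. With 3000 variable genes it was 13.8% of vehicle and 8.44% of AG-120 cells, which turns the contrast, and with 1000 it was 7.41% and 9.90%. Neutrophil-like cells were 6.11% and 2.77% without the fixed markers, and 0% and 0% at resolution 0.5.

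Phase shares moved with the settings below, for which the cause was not tested, although G2/M stayed higher in the AG-120 library in each. Shares in S (vehicle, AG-120) were 36.5% and 45.7% with all barcodes, 35.1% and 41.6% with the strict filter, 34.2% and 37.7% without Scrublet calls, 34.5% and 39.8% at 3250 UMIs, and 35.2% and 26.3% scored within each library. Unthinned AG-120 cells had 52.1% in S and 41.0% in G2/M. Shares in G2/M were 23.7% and 50.5% with the strict filter, 23.7% and 52.0% without Scrublet calls, and 24.0% and 60.4% scored within each library. The AG-120 share was 48.6% at 3250 UMIs and 25.3% with vehicle class shares.

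Median scaling moved every list by its own construction, to 0.22 for S phase, 0.13 for G2/M, −0.66 for brakes, −3.95 for stem cell, −1.05 for HOXA, −1.09 for primary granule, −1.76 for secondary granule, 0.26 for pyrimidine salvage and 0.73 for interferon. With each cell equal, medians were 0.24 for S phase, 0.13 for G2/M, −0.86 for brakes, −3.85 for stem cell, −0.73 for primary granule and −0.85 for secondary granule. Thinned cells gave 0.22, 0.033, −3.85, −0.84 and −1.71 for S phase, G2/M, stem cell, primary and secondary granule. The interferon gamma and MHC list turned to 0.019 with each cell equal, 0.039 with thinned cells and 0.19 with the class weights, and the dendritic list to 0.67, 0.36 and 5.32. The strict cell filter gave −4.00, −1.24 and −2.00 for stem cell, primary and secondary granule. Genes of 50 UMIs or more gave −0.71 for brakes, −3.18 for stem cell and −1.29 for primary granule. With the length trend removed medians were 0.046 for G2/M, −0.90 for brakes, −3.85 for stem cell, −1.02 for HOXA, −1.51 for primary granule, −1.98 for secondary granule and late neutrophil and 0.51 for interferon. Its removal took apoptosis regulators to −0.19, fatty acid metabolism to 0.026 and mast cell/basophil genes to −0.095, across 0, and the cause was not tested. It also took NRF2 targets (0.049), 2-oxoglutarate metabolism (0.15), p53 targets (−0.26) and Tk1 (0.17) under 1.2-fold. Other settings did so for p53 targets (−0.26 with the strict cell filter, −0.18 with median scaling, −0.22 with thinned cells), hypoxia (−0.24 with median scaling, −0.21 with each cell equal), NRF2 targets (0.24 with each cell equal, 0.22 with thinned cells) and interferon gamma and MHC (−0.18 with median scaling). Elane was at 1.03 in log2 with each cell equal, 0.85 with thinned cells and 1.40 with the class weights. The median size of the log2 ratio over genes, 0.49, was 0.48 with the strict filter, 0.49 with all barcodes, 0.50 with median scaling, 0.50 with each cell equal and 0.46 without the length trend.

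Weighting AG-120 classes by vehicle class shares gives the unnamed class, with 69 AG-120 cells, the largest weight by construction. It does not equalise clusters within that class, where cluster 7 held 31 of the 69 AG-120 cells and 242 of the 2682 vehicle cells. The median size over genes was 0.30. Medians were −0.066 for S phase, −0.25 for G2/M, −0.15 for brakes, −1.01 for stem cell, −0.76 for HOXA and −0.043 for pyrimidine salvage. Directions turned for primary granule (0.67), secondary granule (0.80), myeloid factors (0.43), monocyte (0.58), TNF (0.17), immediate early (0.34), p53 (0.17), hypoxia (0.39), RAS/MAPK (0.066) and T/NK (0.85) lists. Besides the S phase, G2/M and pyrimidine salvage medians above, directions also turned for other lists whose main median was under 1.2-fold. These were the unfolded protein response (0.53), glycolysis (0.39) and fatty acid metabolism (0.040) lists. Apoptosis regulators went to −0.23 with each cell equal and to −0.20 with thinned cells, and the cause of these turns was not tested. Without turning, medians came under 1.2-fold for ribosome biogenesis (0.16), purine synthesis (0.016), de novo pyrimidine synthesis (0.12), heat shock (0.10), the TCA cycle (0.12), cholesterol synthesis (−0.065), 2-oxoglutarate metabolism (0.19), megakaryocyte (−0.14) and B lymphoid (−0.18) lists, and log2 ratios for Ncl (0.056), Odc1 (0.25), Gmnn (0.25), Btg2 (−0.12), Lmo2 (0.11) and Idh2 (−0.018). Among named genes log2 ratios turned to −0.58 for Car2, 1.69 for Pf4, 0.79 for Cdkn1a, 0.0071 for Cdkn2d, −0.042 for Cdc6, 0.25 for Gas2l3, 0.73 for Mpo, 1.10 for S100a8, 0.70 for Upp1, −0.074 for Tk1, 0.054 for Pkm, 0.56 for Idh1 and 0.72 for Itgam. Of 771 alternatives of single genes, 456 stayed within the counting interval, 302 moved and 13 turned. Lists within classes moved in 79 of 299 alternatives and turned in 0.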

Other observations

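Tests of free erythroid RNA, of cells from outside the leukemia, of barcode swapping and of both explanations for short transcripts were chosen after the results were seen. An interferon state stood out among the erythroid-like AG-120 cells, in cluster 13. Interferon genes were not left out of the clustering, and this cluster was picked as the erythroid-like one with the highest interferon list. Its higher interferon level thus follows from how it was made and picked, and is a description, not a test. Cluster 13 held 242 AG-120 cells, 6.44% of that library, and 4 vehicle cells. Its type I interferon list reached 3005 CPM (2961 to 3049) in AG-120 cells, against 728 to 864 in the other 4 erythroid-like clusters, and its interferon gamma and MHC list 4329 against 1902 to 3333. Isg15, a ubiquitin-like protein induced by interferon, was at 377.88 CPM in cluster 13 and Irf7 at 147.85, and Rsad2, an antiviral enzyme, at 61.46. The cluster's erythroid list, at 3044 CPM, lay within the range of the others (2485 to 5501), and so did its S and G2/M lists. Deeper cells are argued against as its cause, since its median of 24236.5 UMIs was 1.31 times the lowest median of the other 4 and below the highest, 35237.5. Scrublet cannot decide on doublets with another cell type, since it made 0 calls in the cluster and did not work in these libraries. A doublet should lie between its parents. Cluster 13's interferon list, at 3005 CPM, lay above AG-120 cells of cluster 7 (1892), megakaryocyte-like (1138), neutrophil-like (1011) and cluster 1 cells (820). Thinned AG-120 cells had means of 20.58 UMIs of that list in cluster 13 and 4.03 in cluster 9. Read after the results were seen, these averages argue only against doublets with typical cells of those groups. A rarer cell type is not covered, and the dendritic list was at 4.59 CPM against 0.94 to 3.18 in the other 4. What induced the genes was not tested.

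Markers of other blood lineages were few and unevenly spread. The granulocyte-monocyte progenitor-like cluster 9 was led by Prss34, a basophil protease at 336.38 CPM, beside Elane and Ctsg. Ms4a2, a chain of the IgE receptor at 101.53 CPM, was also among its leading genes. Few cells carried Prss34: without thinning it was seen in 43 of 3756 AG-120 cells, whereas cluster 9 held 303. At resolution 1.5 a mast cell/basophil-like class of 43 AG-120 cells and 1 vehicle cell stood apart, as in some other clusterings. Taken over both libraries cluster 7 held Prg2 at 2225 CPM, with the eosinophil list 6.37 higher in log2 in its AG-120 cells. Over whole libraries the median was 2.17 for 3 measured eosinophil genes and 0.20 for 7 mast cell and basophil genes. Of those 7 genes 3 were higher and 3 lower, and the list sum was lower, at 187.18 AG-120 and 589.54 vehicle CPM. With each cell equal the 2 medians were 3.81 and 1.82, and with thinned cells 3.29 and 0.71. They were 8.12 and 1.30 with the class weights, and 1.87 and −0.095 without the length trend. The median was −0.52 for 4 dendritic genes, −3.14 for 2 lymphoid-primed genes and −3.35 for 2 T/NK genes. Weighted by vehicle class shares the dendritic and T/NK medians turned, to 5.32 and 0.85. The B lymphoid list had 1 measured gene, at −2.08, and the macrophage, plasma cell and stromal lists had 0. Xist, a female-specific RNA, was at 526.50 CPM in erythroid-like and 508.34 in the other AG-120 cells, and had a log2 ratio of −1.15 over the libraries. Erythroid-like clusters 10 and 12 had the T cell receptor genes Trbv13-2 and Tcrg-C1 among their leading genes, and cluster 12 also Gzmb, a cytotoxic granule protease; these genes lie outside the rule for names. Outside the neutrophil-like cluster, 158 kept cells lay in a cluster mostly of the other library. Barcode swapping between the pooled libraries is argued against for these cells, since 0% of them (0 of 158, interval up to 2.31%) shared a barcode with a kept cell of the other library. Barcodes that the cell filter left out were not searched.

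Erythroid-like cells filled the AG-120 library. Deeper sequencing of that library is argued against by thinning, after which 89.6% of its cells were still erythroid-like. Free erythroid RNA as the whole cause is argued against by the neutrophil-like AG-120 cells, whose erythroid list stood at 8.20% of the level in erythroid-like cells (6.51 to 10.2). Cells from outside the leukemia that passed the same sort cannot be told apart from leukemia cells, since the labels give no sex of donor or recipient. Y-linked genes had 9 UMIs, in 3 cells, among 87812558 of the erythroid-like AG-120 cells, and 28, in 14 cells, among 8272074 of the other AG-120 cells; so few cells hold them that most cells of both parts stay unplaced. An effect of AG-120, a difference between the mice, a difference in the sort and a mix-up of samples stay open too, because each treatment has 1 library.

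Ribosome biogenesis genes were higher and cell cycle brakes lower in the AG-120 library. A change of cell mixture was tested within megakaryocyte-like cells, where the ribosome list was at 0.50 (0.46 to 0.53) and the brake list at −0.21 (−0.34 to −0.08), though in cluster 3 of that class thinned cells had near equal means of brake UMIs (5.43 and 5.56). The bound set for the ribosome list, an interval above 0.2, was met, but it took the cells of the class to be alike. The erythroid list was 1.49 higher in the AG-120 cells of that class, so the cells differ in more than the list tested, and the change of mixture cannot be told apart from a change within cells for either list. The ribosome list was at 0.44 in neutrophil-like cells, at 0.45 (0.41 to 0.48) in cluster 1, where the erythroid list was lower (−0.68) but the T/NK list higher (2.06), at 0.16 in erythroid-like cells and at −0.68 in cluster 7; with the class weights its median was 0.16.

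Short transcripts were lower in the AG-120 library in all 5 comparisons. A change of cell mixture is argued against by the neutrophil-like cells, where the median log2 ratio of short transcripts minus that of longer ones was −1.17 (−1.34 to −0.90). Cells of that class were unlike too, but the difference stayed below 0 both where the erythroid list was higher and where it was lower. A loss of short cDNA in preparing the AG-120 library cannot be told apart from a change in the cells. The highest of the differences over 5 comparisons and both gene families was −0.54, as such a loss needs, but genes of 600 to 1500 nucleotides should then not be lower, and all genes of that length were at −0.0088 in cluster 7 and from 0.065 to 0.17 in the other comparisons. The ribosomal protein genes of that length, at −0.47 in cluster 7, go with their whole family, whose longer genes were at −0.48. What keeps the loss open is that library and treatment coincide, so a response of the cells to AG-120 stays untested.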
